A study of Mus musculus with 13 samples.

How the data were processed

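Chondrocytes from mouse rib at postnatal day 1 and from nasal septum at embryonic day 17.5 were fixed with 1% formaldehyde for 10 minutes, and 20000000 cells entered each immunoprecipitation with 9 μg of antibody, per the labels' protocols. Chromatin was sheared to fragments of 100 to 600 bp and libraries were amplified by 18 cycles of PCR. Whether PCR copies were removed before peaks were called is not given in the sources used here. The 13 libraries formed 13 groups of 1, as the labels name a single library per antibody or control and tissue. Peak lists were analysed for the 2 Sox9 libraries, and values from the other 11 libraries, among them the inputs and the IgG control, were not analysed here, so no background was measured the same way.

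The authors deposited 4 peak lists as chromosome, start and end, without height, fold or significance. The genome build was mm9, per the submitters' processing notes. The names of the deposited lists carry the letters FDR with the number 1, without a unit, beside a tag that is not explained. The aligner, the peak caller, what that FDR value stands for, the control library used and the definition of Class I and Class II are not given in the sources used here. With 1 Sox9 library per tissue, each list stems from a single library. Rib peaks on chromosome 7 that end beyond the last gene of GRCm38.p6 numbered 150, so the lists are on another build than that annotation, and no position was converted. Peak positions are the authors' starts and ends, with 1 added to the start. The last Class I line was written with spaces and carried further fields, and its position was read like the others. The number on it, 10829, equals the place of that peak in the whole rib list. Apart from that line, the class lists kept the order of the whole list, and no list held a duplicate peak. Place in the list was used in place of a score, within each list.

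Overlap meant at least 1 shared bp. Shares were given with 95% exact (Clopper-Pearson) binomial intervals. Random overlap came from 1000 placements of the nasal peaks, with their widths, at uniform positions on the same chromosomes within the span covered by peaks. These placements do not model mappability, accessible chromatin or gene density. Classes were compared with two-sided Fisher exact tests, the sample odds ratio and its Wald interval. Clustering was the share of peaks with another peak of the list within 10 kb, edge to edge, against 1000 placements of that list. Class labels were permuted 100000 times for the distribution over chromosomes and for places in the list. For correlations with gene number, peak densities were permuted among the autosomes 100000 times, and for the difference between the classes their standardised densities were swapped at random within chromosomes as often. Windows were fixed bins of 100 kb, to which peaks were assigned by their centres. The odds ratio pooled within 10 bins of the list by place was the Mantel-Haenszel estimate. Regions were named by a rule fixed before the data were examined, the 5 windows with the most peaks in each list, ties by position. The part of that rule that ranks peaks by score could not be applied, as the lists have no score.

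Other settings fixed before the data were examined were an overlap of at least 50% of both peaks, centres within 200 bp, gaps of up to 1 kb, autosomes alone, classes matched on width within 10 width bins, other clustering distances of 5, 25 and 50 kb, and Class II thinned to the number of Class I peaks. Each of these used 200 placements where it needed any. Added after the data were seen were the first 50% of each list by place, equal list lengths, circular shifts of the nasal peaks, pooling within bins, isolated peaks, a clustering distance of 1 kb, thinned Class II at distances other than 10 kb, and windows of 1 Mb or of at least 5 peaks. Comparisons with transcription start sites, gene lists fixed before the data were examined, and SOX motifs need an mm9 genome and annotation and were not run.

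The routines were tested on simulated lists. All 5000 planted overlaps were found, and the calls differed from those of bedtools 2.31.1 for 0 of 27656 peaks, simulated or deposited. The window test called 0 of 10651 windows with no difference planted, where the class of each peak was drawn independently of its neighbours. It called 200 of 200 windows planted with 10 peaks, all Class I, and 0 of 200 planted with 5, so windows with few peaks cannot pass. The draws without a planted difference left out the tendency of neighbouring peaks to share a class, so they do not cover false calls from it. Windows all of Class II, and the rib and nasal comparison, were not simulated. For these, the fewest peaks of a single list that would let a window pass alone were computed. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.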

Results

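The series profiled chromatin of chondrocytes, the cells that make cartilage, from wild-type ICR mice by ChIP-seq. Its 13 libraries comprised 11 from rib chondrocytes taken at postnatal day 1 and 2 from nasal septum chondrocytes taken at embryonic day 17.5. The rib libraries covered the transcription factor Sox9, the histone marks H3K4me2, H3K4me3, H3K27me3, H3K36me3 and H3K27ac, the coactivator p300, RNA polymerase II, 2 inputs and an IgG control, and the nasal libraries covered Sox9 and an input. Sox9 is an HMG-box factor that chondrocytes need in order to form and to make their matrix. The values analysed were 4 lists of Sox9 peaks on mm9. The whole rib list held 27656 peaks, its Class I part 6794, its Class II part 20862, and the nasal list 17440. The lists give positions alone, so the read depth and the strength behind each peak are unknown. There was 1 Sox9 library per tissue and no replicate check was possible. Peaks are not replicates, so every interval and test below compares these lists and covers counting error alone, and tissue and stage differ together between them.

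The rib peaks divided into 2 classes without remainder. Class I held 24.6% of the rib peaks and Class II 75.4%, no peak stood in both or in neither, and 1 Class I peak shared bases with a Class II peak. How the submitters drew the classes is not given in the sources used here. The question behind the series, from its title, is whether Sox9 works through distinct regulatory programmes. Peak widths were similar, with a median of 177 bp in Class I, 181 bp in Class II and 182 bp in the nasal list. Class I peaks stood later in the rib list than Class II peaks. Their median place was 16983.5 against 12631, and a Class I peak followed a Class II peak in 0.623 of all pairs (two-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). Among the rib peaks that a nasal peak overlapped, this probability was 0.762. That higher value restates the steeper fall of nasal overlap along the list in Class II, given below. What the order of the list stands for is not given in the sources used here.

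To compare Sox9 occupancy between the 2 cartilages, rib and nasal peaks were intersected. Of the 27656 rib peaks, 11847 shared at least 1 bp with a nasal peak, or 42.8% (95% exact binomial interval 42.3% to 43.4%). Of the 17440 nasal peaks, 11899 shared at least 1 bp with a rib peak, or 68.2% (67.5% to 68.9%). Random placement of the nasal peaks on the same chromosomes met 78.0 rib peaks on average and 108 at most over 1000 placements. The observed overlap was 152 times that average. Uniform placement ignores where chromatin is accessible, so this excess does not tell shared Sox9 sites from other shared features of chromatin. Class I peaks met 27.0% of the nasal peaks and Class II peaks 41.2%, and 6 nasal peaks touched both classes. Centres of shared peaks lay a median of 35 bp apart, with 63.2% of them within 50 bp, 57.6% in Class I and 66.8% in Class II. Sharing a base already keeps the centres of such narrow peaks near each other. When at least 50% of both peaks had to be shared, the rib share was 28.4% and the nasal share 45.1%. No rib peak lay within 1 kb of 3821 nasal peaks, 21.9% of that list.

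Class I peaks were overlapped by nasal peaks far more often than Class II peaks. Nasal peaks overlapped 4677 of the 6794 Class I peaks, or 68.8% (67.7% to 69.9%), and 7170 of the 20862 Class II peaks, or 34.4% (33.7% to 35.0%). The difference was 34.5 percentage points and the odds ratio 4.22 (95% interval 3.98 to 4.47). The p of a two-sided Fisher exact test was too small for the software to return. Random placement gave at most 0.515% for Class I and 0.398% for Class II. The odds ratio was 2.21 when at least 50% of both peaks had to be shared, where the shares were 41.4% and 24.2%. It was 6.93 when peaks up to 1 kb apart counted, where the shares were 81.9% and 39.5%.

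The overlap with nasal peaks declined along the rib list, and steeply so for Class II. The list was divided by place into 10 bins of equal size. In bin 1, nasal peaks overlapped 87.8% of the 221 Class I peaks (82.7% to 91.8%) and 81.1% of the 2545 Class II peaks (79.6% to 82.6%). In bin 5 the shares were 76.2% and 27.6%. In bin 10 they were 49.0% (45.9% to 52.1%) and 10.2% (8.85% to 11.7%). The share of Class I among the peaks of a bin rose over the same range from 7.99% to 36.7%. The odds ratio was 1.67 (1.10 to 2.53) in bin 1 and lay between 6.76 and 11.1 in the later bins. Pooled within bins, it was 8.27 (7.71 to 8.87). The overlap declined along the nasal list as well, where rib peaks overlapped 93.1% of bin 1 and 42.4% of bin 10. There the larger fall was that of Class I, which overlapped 41.7% of bin 1 and 9.75% of bin 10, whereas Class II overlapped 51.5% and 32.7%. Shared peaks held related places in both lists, with a Spearman correlation across peaks of 0.384 over all of them, 0.491 in Class I and 0.517 in Class II.

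**Figure D1:**
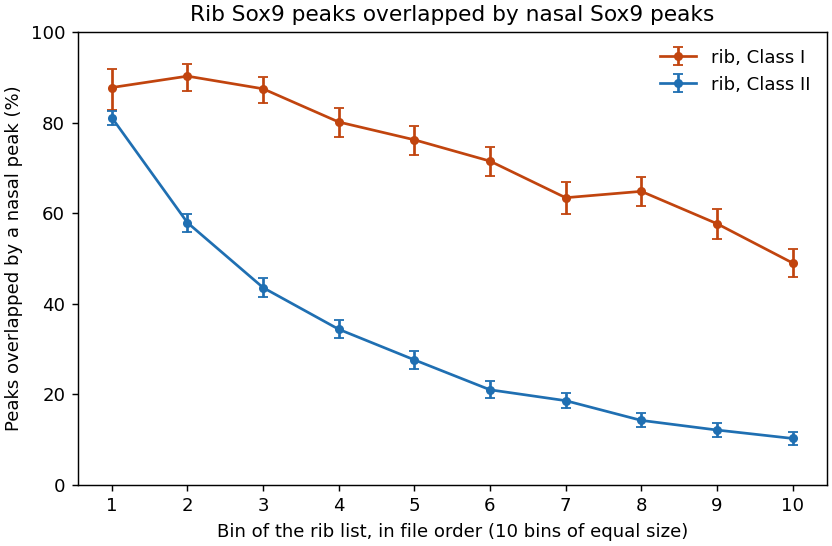
Share of rib Sox9 peaks overlapped by at least 1 bp of a nasal Sox9 peak (%), by bin of the rib list in file order (10 bins of equal size), for Class I and Class II; bars are 95% exact binomial intervals. The Class I share runs from 87.8% to 49.0% and the Class II share from 81.1% to 10.2%.

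Sox9 peaks lay in clusters in every list. Neighbouring peaks that shared bases counted as clustered. Pairs of adjacent peaks that shared bases numbered 130 in the rib list, 60 in Class I, 69 in Class II and 168 in the nasal list. Whether single enrichments were split into several peaks was not tested. Another peak of the same list stood within 10 kb of 52.9% of rib peaks, 39.3% of Class I peaks, 49.6% of Class II peaks and 44.9% of nasal peaks. Random placement of each list gave at most 21.8%, 7.07%, 17.3% and 15.2% over 1000 placements. At that distance Class I peaks were clustered less often than Class II peaks, with an odds ratio of 0.658 (0.622 to 0.695, two-sided Fisher exact test, p = 7.93e-50). Peaks that neighbour each other count as clustered together and are not independent. The intervals in this paragraph are therefore too narrow and the p too small. The direction of the difference between the classes turned with list length, and at the full length of Class II also with distance. Class II thinned at random to the number of Class I peaks gave 22.8% at 10 kb, and the odds ratio of Class I over it was 2.19 (2.03 to 2.36). Within 1 kb, 25.1% of Class I peaks and 15.1% of Class II peaks had a neighbour of their class, with an odds ratio of 1.89 (1.77 to 2.02). Within 50 kb the shares were 62.5% and 81.2%, with an odds ratio of 0.385, and thinned Class II gave 53.7%, which turned the odds ratio to 1.44 (1.34 to 1.54).

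Class I and Class II peaks neighboured each other less often than shuffled labels did. If the classes were drawn by distance to genes, this follows from how they were drawn. A Class II peak stood within 10 kb of 23.9% of Class I peaks, whereas shuffling the class labels among the rib peaks of each chromosome gave 43.7% to 46.4% over 200 shuffles. A Class I peak stood within 10 kb of 8.12% of Class II peaks, against 19.2% to 20.6% in the shuffles. Neighbours of the same class were more frequent than in the shuffles, which gave 18.7% to 21.9% for Class I and 44.3% to 45.7% for Class II. Chains of at least 5 rib peaks spaced at most 10 kb apart numbered 447 and held 2880 peaks, 10.4% of the list. Random placement gave at most 11 such chains. A nasal peak lay in 424 of the 447 chains. As 42.8% of all rib peaks were overlapped and each chain held at least 5, a high count follows from that share alone.

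**Figure D2:**
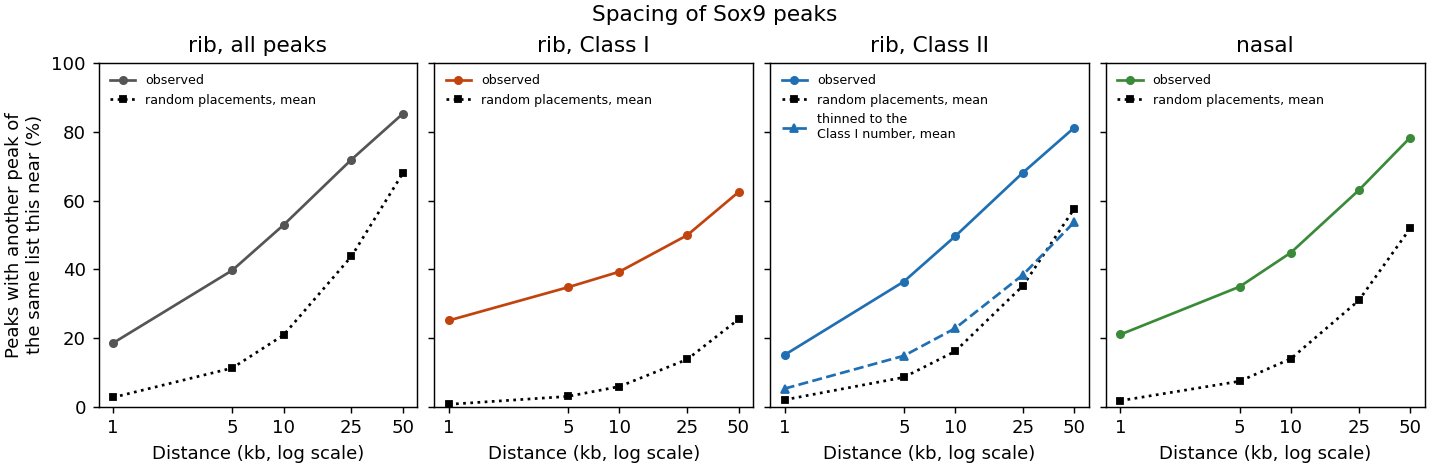
Share of peaks (%) that have another peak of the same list within 1, 5, 10, 25 or 50 kb (log axis), for the rib list, its classes and the nasal list; solid lines are observed, dotted lines the mean of random placements of the same list, and the dashed line the mean of Class II thinned to the Class I number. At 10 kb the observed shares are 52.9%, 39.3%, 49.6% and 44.9%, and thinned Class II is at 22.8%.

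The densest rib region was the window at chromosome 15, 97800001 to 97900000 (all positions mm9, 1-based), with 37 rib peaks and 16 nasal peaks. It ranked first for Class II as well, with 27 peaks, and held 10 Class I peaks. The Class I peaks formed a chain of 6.58 kb from 97828818 to 97835393, with 3 nasal peaks in it, and the Class II peaks lay on both sides. On chromosome 6, 37300001 to 37400000 held 24 rib peaks, of which 22 were Class II, and 13 nasal peaks. On chromosome 19, 5800001 to 5900000 held 24 rib peaks, of which 9 were Class I, and 23 nasal peaks, the most of any nasal window. On chromosome 7, 124600001 to 124700000 held 18 peaks, all Class II, beside 10 nasal peaks. On chromosome 2, 32700001 to 32800000 held 17 rib peaks, of which 15 were Class II, and 12 nasal peaks. The other leading Class II windows, chromosome 17 at 45900001 to 46000000 with 17 peaks and chromosome 3 at 27500001 to 27600000 with 16, held no Class I peak, and held 8 and 9 nasal peaks.

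**Figure D3:**
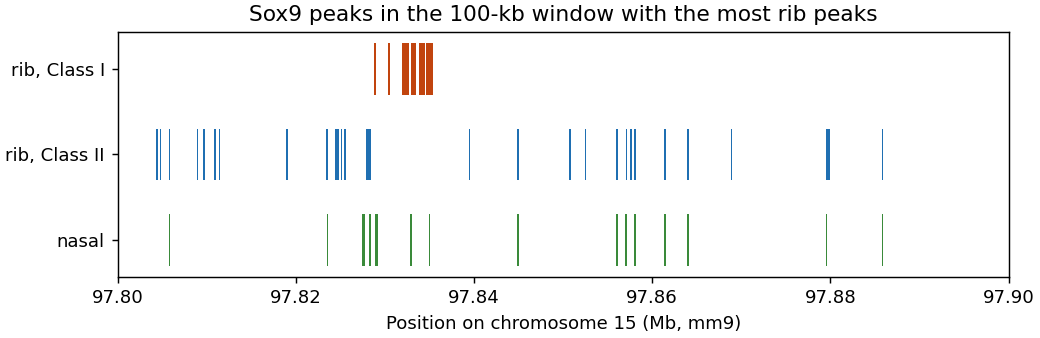
Map of Sox9 peaks in the window at chromosome 15, 97800001 to 97900000 of mm9 (x axis, position in Mb), with rows for rib Class I, rib Class II and nasal peaks drawn to scale, so that peaks of a few bp fall below the resolution of the picture. The 10 Class I peaks lie together between 97828818 and 97835393, with Class II peaks on both sides.

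The leading Class I windows lay elsewhere. The window at chromosome X, 166400001 to 166500000 held 15 Class I and 2 Class II peaks beside 12 nasal peaks, and its Class I peaks spanned 12.6 kb. Whether reads from repeated sequence fell in that span was not tested. On chromosome 11, 68800001 to 68900000 held 13 Class I and 3 Class II peaks, of which nasal peaks overlapped 13 in all. On chromosome 13, 23600001 to 23700000 held 13 Class I peaks, 1 Class II peak and 12 nasal peaks. On chromosome 7, 26000001 to 26100000 held 11 Class I peaks, 2 Class II peaks and 12 nasal peaks. On chromosome 17, 39900001 to 40000000 held 11 Class I peaks within 5.59 kb, no Class II peak and no nasal peak, and whether reads from repeated sequence fell there was not tested. Among nasal windows, chromosome 8 at 86700001 to 86800000 came second with 17 nasal peaks, where the rib list had 10. Gene names for these windows were not used here.

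Windows rich in rib peaks were often rich in nasal peaks. Rib and nasal lists together occupied 11416 windows of 100 kb, 7434 of which held peaks of both, 3217 of the rib list alone and 765 of the nasal list alone. The 100 windows with the most peaks in each list had 40 in common, where windows drawn at random would give 0.876. Fisher exact tests with Benjamini-Hochberg adjustment called no window between rib and nasal lists, and 21 of the 11416 had an unadjusted p under 0.05. That count says little about single windows, because a window would have needed 27 rib peaks without a nasal peak, or 13 nasal peaks without a rib peak, to pass alone. Between Class I and Class II, 8 of 10651 windows passed as richer in Class I. None passed as richer in Class II. Passing alone in that direction would have taken 46 Class II peaks without a Class I peak, and the fullest window held 37 rib peaks. Fewer suffice where other windows pass, and how many was not computed. The windows that passed included the windows named above on chromosomes X, 11, 13, 17 and 7. The smallest adjusted p, 0.000608 by the Fisher exact test, belonged to the window on chromosome X. The tests took peaks as independent, whereas neighbouring peaks tended to share a class. The p-values of the class windows are therefore too small, and the counts of windows that passed may be too high. On windows of 1 Mb, 134 differed, 104 of them richer in Class I and 30 richer in Class II. These counts are not comparable between the directions, because a window needs more Class II than Class I peaks to pass. Passing alone took 8 Class I peaks, which 1280 of the 2126 windows could hold, or 40 Class II peaks, which 55 could hold. Fewer suffice where other windows pass, so these are not the numbers of windows that were able to pass.

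Sox9 peaks were spread unevenly over the chromosomes. Chromosome 11 had the highest density of every list among the autosomes, with 16.3 rib peaks per Mb and 11.4 nasal peaks per Mb, and chromosome 12 the lowest, with 9.01 and 5.23. Chromosome X stood far below, with 1.82 rib peaks and 1.02 nasal peaks per Mb, or 0.159 (95% Poisson interval 0.142 to 0.179) and 0.142 (0.121 to 0.165) of the autosomal density. The Class I share of rib peaks ranged from 19.4% on chromosome 18 to 32.3% on chromosome 7. The chi-square of class over chromosomes was 217, against at most 54.4 when class labels were permuted (permutation p = 1e-05, the smallest that 100000 permutations can give). Leaving chromosome X out gave 209. The permutation moved labels peak by peak, whereas neighbouring peaks tended to share a class, so the permuted spread is too narrow.

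Class I density followed the number of genes on a chromosome more closely than Class II density did. Protein-coding genes were counted per chromosome in the RefSeq table of GRCm38.p6, with no use of its coordinates. Over the 19 autosomes, Pearson's r between genes per Mb and peaks per Mb was 0.921 for Class I (permutation p = 1e-05, adjusted 2e-05) and Spearman's rho 0.944 (permutation p = 1e-05, the smallest possible for both). For Class II, r was 0.561 (permutation p = 0.013, adjusted 0.013) and rho 0.461 (permutation p = 0.048). For the nasal list, r was 0.864 and rho 0.877, each with a permutation p of 1e-05 and an adjusted p of 2e-05 for r. For the whole rib list, r was 0.771 (permutation p = 0.00019, adjusted 0.00025) and rho 0.732 (permutation p = 0.0005). These 4 lists made up the family for adjustment. The difference in r between the classes was 0.361 (two-sided permutation test swapping the classes within chromosomes, p = 0.0058). Without chromosomes 7 and 11, the farthest from the median in gene density, r was 0.931 for Class I, 0.685 for Class II, 0.894 for the nasal list and 0.83 for the rib list. Chromosomes are not replicates, and if the classes were drawn by distance to genes, the relation follows from how they were drawn.

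**Figure D4:**
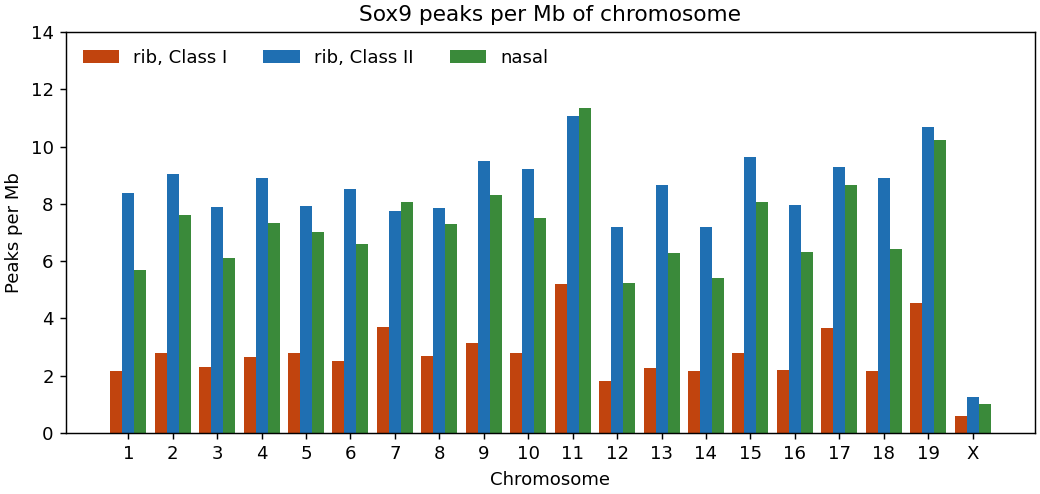
Sox9 peaks per Mb on each chromosome for rib Class I, rib Class II and the nasal list, as bars from 0; the length of a chromosome is the span covered by peaks. Chromosome 11 is the highest autosome and chromosome X, with 0.579, 1.24 and 1.02 peaks per Mb, the lowest of all.

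A gene name stood beside 1 peak of the lists. The last line of the Class I list placed a peak of 486 bp at chromosome 11, 100256750 to 100257235, and named Jup, which encodes junction plakoglobin, a protein of cell junctions. The transcript accession on that line belongs to Jup in the GRCm38.p6 table, where its protein-coding neighbours are Hap1 and P3h4. A nasal peak shared 136 bp with this peak, and a Class II peak shared 162 bp with it. Within 10 kb lay 2 further Class II peaks and 1 further nasal peak. This line was chosen because it carried a name, outside the rule for named regions.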

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

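Of 58 recomputed values, 50 kept their direction and their side of the threshold. Among these, the nasal overlap with both classes together could not change, as the classes make up the whole rib list. Circular shifts changed only the random set, and autosomes alone left out 1.06% of rib peaks. Rib and nasal overlap stayed above the highest random placement under each alternative run, with rib shares from 28.4% to 51.9% and nasal shares from 45.1% to 78.1%. The odds ratio of Class I over Class II for nasal overlap ranged from 2.21 to 8.27, was 4.29 with classes matched on width and 4.23 on autosomes. Clustering stayed above random placement for every list and distance run. The odds ratio of Class I over Class II for clustering reversed to 1.89 at 1 kb, where the cause was not tested, and with Class II thinned to the number of Class I peaks, which removes the difference in list length. The thinned odds ratios were 6.03 at 1 kb, 3.05 at 5 kb, 2.19 at 10 kb, 1.60 at 25 kb and 1.44 at 50 kb. At equal numbers the direction therefore did not turn with distance, and the lower clustering of Class I from 5 to 50 kb went with list length. Windows that differed between the classes numbered 8 at 100 kb, 134 at 1 Mb, where the cause was not tested, and 43 among windows with 5 or more rib peaks, where fewer windows were tested. All these tests took neighbouring peaks as independent. At 100 kb no window passed as richer in Class II. Passing alone took 46 Class II peaks there, or 40 among windows with 5 or more rib peaks, and the fullest window held 37 rib peaks. Fewer suffice where other windows pass. The 1 kb distance, thinning at distances other than 10 kb, the window comparisons, place in the list, chromosomes without X for the class distribution, the first 50% of each list, equal list lengths, circular shifts, isolated peaks and pooling within bins of the list were chosen after seeing the data. Alternatives that needed a score (the better part of each list, equal numbers of top-scored peaks, score by class) were not run, nor were those for transcription start sites, gene lists, SOX motifs and peaks near Hox, craniofacial and trunk genes. No paired analysis was possible because each group has 1 library. The unknown depth of each library limits every comparison of list lengths.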

Other observations

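Some windows of 100 kb held peaks of a single tissue, without passing adjustment for the 11416 windows tested, which few windows could pass. They were picked after their values were seen. Chromosome 15 at 96700001 to 96800000 held 10 Class II peaks and no nasal peak (Fisher exact p = 0.00878, adjusted p = 1). Chromosome 6 at 52100001 to 52200000 held 5 Class I and 3 Class II peaks and no nasal peak (Fisher exact p = 0.0268, adjusted p = 1). The same p belonged to windows of 8 Class II peaks without a nasal peak on chromosomes 2, 4 and 9. Nasal peaks without any rib peak were at most 4 per window among those with the smallest p, as on chromosome 11 at 77500001 to 77600000 and chromosome 9 at 40600001 to 40700000. The 11 Class I peaks on chromosome 17 between 39979975 and 39985565 were separated by a median of 117.5 bp, with no nasal peak among them, and whether reads from repeated sequence fell there was not tested. Within chromosome X, 15 of its 93 Class I peaks lay between 166424727 and 166437298.

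Some tests below were chosen only after the results they bear on had been seen in part. These were place in the list, isolated peaks, X copy number, gene number on X, peak boundaries, equal list lengths and nasal depth. Class I peaks were overlapped by nasal peaks more often than Class II peaks. The tables argue against place in the list as the cause, since Class I stood later and the odds ratio pooled within bins was 8.27 (7.71 to 8.87). They argue against peak width, as the odds ratio with classes matched on width was 4.29 (3.997 to 4.61). They also argue against crowding over distances of 2 to 5 kb. Moving all nasal peaks that far left a difference of at most 0.611 percentage points, against 34.5 unmoved. These shifts pass over crowding within 1 kb and cannot judge it. Rib peaks with no other rib peak within 10 kb gave an odds ratio of 6.32 (5.79 to 6.91), which argues against crowding of rib peaks. Crowding of nasal peaks within 1 kb was not tested. Also open and untested is a signal common to chromatin of both tissues at Class I positions, whether from Sox9 or from the assay. Values from the inputs and the IgG control were not analysed here.

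Chromosome X carried few peaks in every list. A proportional loss from a single X copy would leave a ratio of 0.5 to the autosomes, and the rib ratio was 0.159 (0.142 to 0.179). Gene number falls short as well, with 0.0963 Class I peaks per protein-coding gene on X (0.0777 to 0.118) against 0.272 on the lowest autosome. A weaker signal on X against a fixed threshold may contribute and cannot be told apart, as the odds ratio of lying on X in the first against the second part of the rib list, split at its middle, was 0.835 (0.662 to 1.05). The sex of the animals is not given in the sources used here, and neither mappability nor a biological explanation was tested.

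Most rib peaks shared no base with a nasal peak. Different peak boundaries do not account for this, because 12.4% of the 15809 such peaks (11.9% to 13.0%) lay within 1 kb of a nasal peak, 42.0% in Class I and 7.86% in Class II. For the length of the nasal list, the first 17440 rib peaks were taken, as many as the nasal list holds. Of these, 42.6% (41.8% to 43.3%) had no nasal peak within 1 kb, against 50.1% of the whole list. This speaks against list length only if both lists rank peaks in a shared order, which is not known, so list length is not excluded. A lower depth of the nasal library cannot be told apart from a difference in tissue and stage. In bin 1, 15.1% of rib peaks (13.8% to 16.5%) had no nasal peak within 1 kb and 3.33% of nasal peaks (2.53% to 4.28%) no rib peak, which either would give, and the limit of 10% set beforehand for rib bin 1 decides nothing because the depths are unknown.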
